A study of Mus musculus with 6 samples.

How the data were processed

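Single-nucleus RNA sequencing (10x Chromium) was done on kidney cortex of FVB/N mice. There were 3 control libraries (Klf4 fl/fl) and 3 knockout libraries (Klf4 fl/fl with a podocyte-specific Cre, the recombinase that removes Klf4). Per the labels, kidneys were perfused and kept in RNALater, and nuclei were freed with a detergent buffer and filtered before loading. The labels name no batch, day or litter, and they do not give the exons of Klf4 that the recombinase removes.

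The authors made the deposited matrices with Cell Ranger 3.1.0 (per the file headers) on genome build mm10, and the matrices hold raw UMI counts per gene and barcode with no normalization. Seurat is named in the labels without its role. The other deposited files list the barcodes and 31053 genes, and hold no measurement. Aligner settings, annotation release and the settings of barcode calling were not given in the sources used here. No cell type annotation was used here, so cell types were rebuilt from the counts, and a difference from the study may come from the rebuilt names.

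Barcodes with at least 300 genes and at most 5% of UMIs from mitochondrial genes were kept. Doublets were scored per library with Scrublet (scanpy 1.11.5). Its automatic threshold called 1043 barcodes in 1 library and 0 to 2 in each of the others. The highest scores were therefore removed at a rate of up to 0.8% per 1000 barcodes, a choice made after the data were examined. Barcodes tied at the limiting score were kept, so the 4 libraries numbered 2 and 3 lost 2.24 to 3.89% against 3.14 to 4.86% at the full rate. This took 3443, 86 and 162 barcodes from controls 1, 2 and 3, and 3866, 150 and 236 from knockouts 1, 2 and 3.

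Counts were scaled per nucleus, log-transformed and centred per library on 3000 variable genes, without mitochondrial and sex-linked genes. Leiden clustering (igraph 0.11.9) used 30 components, 20 neighbours and resolution 1.5 for all nuclei. Nuclei outside the proximal tubule were clustered again with 40 components, 15 neighbours and resolution 2.5, for 62 clusters in all. Clusters of all nuclei in which no class but the proximal tubule reached a score of 0.3 were taken as proximal tubule. Any other cluster took a name from the fixed marker genes on at least 3 detected markers and a mean log2 ratio to all other nuclei of at least 1.0, measured in control nuclei where these were enough. A cluster in which a second class with at least 3 detected markers reached 0.5 of the first score was called mixed. Related classes were exempt, such as podocyte with parietal epithelial cell, connecting tubule with principal cell, injured tubule with other tubule classes or parietal epithelial cell, and cycling cells with any class. A named cluster, injured tubule and cycling aside, was also called mixed where its proximal tubule markers were high and another cluster of its name had them lower. The largest mixed cluster, of thick ascending limb with proximal tubule, was set aside by this second rule. A cluster stayed unnamed where its 10 leading genes held more markers of another class than of its own, with pooled classes counted as 1. These thresholds were set after the clusters were seen. Each name below stands for a class that is like that cell type by its markers. Mesangial, mural and fibroblast nuclei were pooled, and so were immune nuclei. Shares of nuclei were taken from a second clustering, of 60 clusters. It left out the 432 genes called in any class, with or without the replicate number as a block, but not those called under other alternatives alone.

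Raw UMI counts were summed per library and class, in classes with at least 10 nuclei in a library. Sums were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, low-count filter by group, no covariate) at a Benjamini-Hochberg adjusted p of 0.05. Fold changes are those of the fit, knockout over control, which can differ from the ratio of the mean CPM, with the standard error (SE) on the log2 scale. CPM is UMIs scaled in the usual way to the UMI total of the class in a library, given as mean ± SD over n = 3 libraries. The 22 gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01) where at least 5 members were tested, with adjustment over all lists and classes together. Shares were compared with a two-sided exact permutation test over 20 assignments, whose smallest p is 0.1. The thin limb class had too few control nuclei for a test, and the injured tubule and cycling classes were compared as shares alone.

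The tests, gene lists, markers, nucleus filter and rule for naming genes were fixed before the data were examined. Klf4, Nphs1, Wt1, Stat3 and Cd44 are named in podocytes and parietal epithelial cells whatever their values. In each class the rule names up to 10 genes that rose and 10 that fell with the smallest p, leaving out clone, mitochondrial and ribosomal names. From a list that describes a class it names up to 4 members past the threshold, or the 2 with the smallest p as values. In a class with no gene past the threshold it gives up to 5 genes as values.

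On data simulated for 6 of the 11 comparisons (all nuclei, podocytes, parietal epithelial cells, proximal tubule, endothelial and immune cells), with 200 changed genes each, the edgeR test recovered 11 to 25% of changes of 2-fold and 61 to 82% of changes of 4-fold. Of the calls, 2.91 to 12.2% were false. In these 6 a change of 2-fold was missed more often than found. The other 5 were not simulated. Intervals and limits from counts cover counting error alone.

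Samples of 1 number deviated together over all genes: the deviations from the group means correlated at 0.71, 0.40 and 0.46 in pairs 1, 2 and 3 of all nuclei. The numbers were therefore taken to pair the samples, and the fit with the replicate number as a block is given where it changed a call. The pairing came from these correlations, since the labels name no pairs. Beside the number, each title carries a code, with the letter A in all 3 controls, E in knockout 1 and C in knockouts 2 and 3. These letters part the groups and do not follow the pairing, and their meaning is not given. Control 2 correlated with knockout 3 at 0.42, and control 3 with knockout 2 at 0.45, so libraries 2 and 3 form a batch as much as 2 pairs. Both libraries numbered 1 had many more barcodes than the others, a larger mitochondrial share and a larger share of Malat1.

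Alternatives were the replicate block, DESeq2 1.42.0, RLE scaling, no low-count filter, at least 500 genes per nucleus, doublets kept, classes by the highest marker score, leaving out each library, and leaving out both libraries numbered 1. After the data were examined, classes rebuilt without the called genes were added, as was clustering with them for the shares. A sex covariate was not run, since Y-linked genes were read in all 6 libraries. Lists were also tested with an estimated correlation and with fry. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and R 4.3.3.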

Results

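Nuclear RNA of the kidney cortex was counted in single nuclei of 3 control mice and 3 mice in which a podocyte-specific Cre removes Klf4 from podocytes, the filtering cells of the glomerulus. The comparison asks what the loss of this transcription factor from podocytes does in podocytes and in the rest of the cortex. The files held 21957, 3919 and 5318 barcodes in controls 1, 2 and 3, and 22080, 5089 and 6079 in knockouts 1, 2 and 3. Total UMIs were 62016616, 8270961 and 12393161 in the controls and 52478581, 9356394 and 12604832 in the knockouts. After filtering, 16202, 3759 and 5072 control nuclei and 18203, 4932 and 5828 knockout nuclei remained. Median UMIs per barcode were 1978, 1109 and 1813.5 in the controls and 1638, 1309 and 1531 in the knockouts. The median mitochondrial share was 2.67% and 1.02% of UMIs in control 1 and knockout 1, and 0.0870 to 0.163% in the other libraries. Control 1 and knockout 1 thus stood apart in number of barcodes, total UMIs and mitochondrial share, and values within them (pair 1) and within libraries 2 and 3 are given where they matter.

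Klf4 (ENSMUSG00000003032), the zinc-finger transcription factor that the Cre targets, was read too rarely in podocytes to compare. The 3 control libraries held 1 Klf4 UMI in podocytes and the 3 knockout libraries 4. Its level was 1.39 ± 2.40 CPM in control and 8.19 ± 7.10 CPM in knockout podocytes (n = 3 per group, exact permutation p = 0.4, smallest p 0.1). A group total of 3 UMIs would stand for 8.10 CPM in the controls and 7.90 CPM in the knockouts, so a loss was not detectable at this depth. Which exons are removed was not given in the sources used here, and counted reads may lie outside them. Endothelial nuclei, which were not targeted, held 28.0 ± 13.8 CPM of Klf4 in the controls and 41.3 ± 25.8 CPM in the knockouts (exact permutation p = 0.4, n = 3).

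Measured as a fold, the shares of injured tubule and cycling nuclei differed most between the groups. Injured tubule nuclei made up 0.368 ± 0.117% of control nuclei and 6.66 ± 2.46% of knockout nuclei (n = 3 per group), an 18.1-fold higher mean. The leading genes of its clusters took in C3, Vcam1, Cxcl10 and Havcr1, genes of complement, cell adhesion, interferon response and proximal tubule damage. Cycling nuclei, led by Top2a, Lockd and Prc1, made up 0.0815 ± 0.0246% and 1.98 ± 0.946%, a 24.3-fold higher mean. The cycling share depended on the clustering: with the called genes among the clustering genes the class held 928 nuclei instead of 456, and the difference was 3.81 percentage points instead of 1.90. In both classes every knockout library lay above every control (exact permutation p = 0.1, the smallest that 3 against 3 can give, adjusted to 0.65 over 13 classes). The differences were 8.02 and 0.814 percentage points in pair 1, and 5.43 and 2.44 within libraries 2 and 3. In edgeR fits on nuclei per class, both classes passed, at log2 changes of 4.14 and 4.52 (adjusted p = 5.7e-08 for each), and the other 11 did not. A fit with the replicate block gave 4.12 and 4.29 (adjusted p = 7.8e-07 for each).

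In the other 11 classes the libraries of the 2 groups overlapped. Podocytes made up 1.16 ± 0.446% of control and 1.34 ± 0.0928% of knockout nuclei (exact permutation p = 0.4, n = 3). Parietal epithelial cells, the lining of Bowman's capsule, made up 0.262 ± 0.135% and 0.381 ± 0.164% (exact permutation p = 0.3). That difference of 0.119 percentage points depended on the naming, and was 3.02 with classes by the highest marker score (exact permutation p = 0.1). Proximal tubule nuclei made up 57.2 ± 14.8% and 45.1 ± 8.38% (exact permutation p = 0.3), and immune nuclei 0.466 ± 0.347% and 0.827 ± 0.338% (exact permutation p = 0.3). Mixed clusters held 10.4% of control and 13.4% of knockout nuclei, and unnamed clusters 4.76% and 5.89%. An unnamed cluster led by Cd44 and another with Dcdc2a among its leading genes may hold further injured nuclei. Of the 13 classes, 2 had control and knockout libraries that did not overlap, where chance gives 10%. That count was 6 without control 1, 4 without control 2, 4 without control 3 and 3 without knockout 1, and 7 without both libraries numbered 1. With 2 libraries against 3 chance gives a fraction of 0.2, and with 2 against 2 of 0.333. The share of a class also depends on how well its nuclei come free of the tissue.

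**Figure D1:**
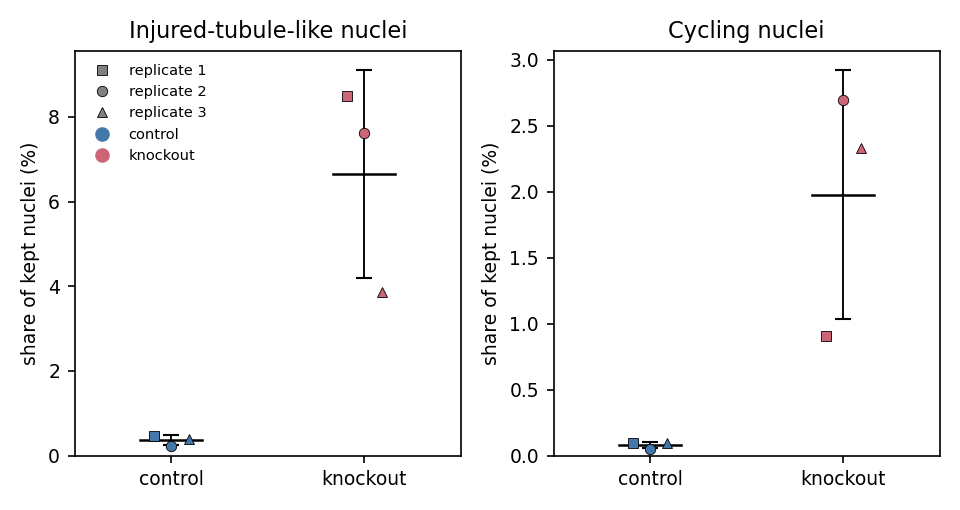
Share of kept nuclei (%) in the injured tubule and cycling classes of each control and knockout library, with a point per library and bars for the mean ± SD (n = 3). Injured tubule nuclei averaged 0.368% in the controls and 6.66% in the knockouts, and cycling nuclei 0.0815% and 1.98%, with no overlap in either class.

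In podocytes, 12 genes rose and 3 fell among 1986 tested (edgeR, adjusted p under 0.05). The rises were led by Epha6 (ENSMUSG00000055540), an ephrin receptor, and Rbfox1 (ENSMUSG00000008658), an RNA splicing factor best known in neurons. Epha6 rose 15.4-fold, from 360.4 ± 167 to 5643 ± 1395 CPM (log2 3.94 ± 0.40 SE, adjusted p = 0.00541, n = 3 per group). Rbfox1 rose 23.6-fold, from 243 ± 139 to 6089 ± 2585 CPM (log2 4.56 ± 0.49 SE, adjusted p = 0.00703). The transcription factor Npas3 rose 16.0-fold (log2 4.00 ± 0.51 SE, adjusted p = 0.00833). Frem1, a basement membrane protein, rose 15-fold (log2 3.91 ± 0.56 SE, adjusted p = 0.0167). Other genes rose less. They were Plod2, which modifies collagen for cross-linking (log2 1.81 ± 0.32 SE), Tpm1, a tropomyosin of actin filaments (1.56 ± 0.28), and Srgap3, a gene of neuron migration (3.09 ± 0.56). Nckap5 (log2 2.35 ± 0.43 SE), the chromatin protein Setd5 (1.44 ± 0.27) and the junction scaffold Magi3 (1.83 ± 0.35) also rose, at adjusted p from 0.0438 to 0.0476 for these 6. Xkr4 (log2 2.63) and Gm47283 (1.56), chosen after their values were seen, were the other rises. Klhl32 fell by 1.97 ± 0.33 (SE) on the log2 scale, the adhesion protein gene Opcml by 1.54 ± 0.28 and the astrotactin gene Astn2 by 1.56 ± 0.29 (adjusted p = 0.0430 to 0.0438).

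The genes of podocyte structure and identity did not pass as a group. Of 28 tested members 0 passed over all genes and 0 adjusted over the list alone (edgeR; 17 were higher and 11 lower; camera adjusted p = 0.453). Nphs1, which encodes nephrin of the slit diaphragm, read 1941 ± 784 and 1872 ± 516 CPM (log2 -0.05 ± 0.33 SE, adjusted p = 0.966). Wt1, a podocyte transcription factor, read 1468 ± 187 and 1133 ± 235 CPM (adjusted p = 0.606). The smallest p values of the list were those of Thsd7a (log2 -0.79 ± 0.21 SE, adjusted p = 0.171) and Myo1e, a podocyte myosin (0.86 ± 0.30, adjusted p = 0.353). The list passed without control 1 (camera adjusted p = 0.00739) and without both libraries numbered 1 (0.0136), toward higher values. Of 5 matrix and fibrosis genes 0 passed over all genes and 2 did adjusted over the list alone. They were Ctgf (log2 2.41 ± 0.59 SE, adjusted p = 0.153 over all genes) and the collagen cross-linker Loxl2 (1.81 ± 0.55, 0.288). That list (camera adjusted p = 0.488) passed without knockout 1 (0.0036) and without both libraries numbered 1 (0.026). Of 7 JAK-STAT3 genes 0 passed (camera adjusted p = 0.783), among them Stat3 (log2 0.13 ± 0.36 SE, adjusted p = 0.923), Jak1 (0.45 ± 0.27) and Bcl2l1 (0.57 ± 0.47). Cd44 had 2 control and 11 knockout UMIs in podocytes, a ratio of levels of 5.36 (95% counting interval 1.17 to 49.8), and was not tested.

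In podocytes, 202 genes had an unadjusted p under 0.05. For each called gene of this and the other classes all 3 knockout libraries lay on 1 side of all 3 controls. Genes picked for a group difference tend to do so, and the 10% that chance gives holds for genes not picked. The count of 15 rested on the full set of libraries. It was 2 without control 1, 3 without control 3, 5 without knockout 3 and 294 without knockout 1. It was 0 without control 2 or knockout 2, with 173 and 142 genes at an unadjusted p under 0.05. It was 239 without both libraries numbered 1, the 15 among them. With doublets kept it was 5, all among the 15, and with classes by the highest marker score 14, of which 4 were. The adjusted p with the replicate block was 0.0838 for Tpm1 and 0.0830 for Setd5. Proximal tubule transport genes, which podocytes do not use, were lower in knockout podocytes for 15 of 17 members (camera adjusted p = 0.00451, adjusted p = 0.676 with an estimated correlation). Slc3a1 (log2 -1.52 ± 0.38 SE) and Slc7a13 (-1.25 ± 0.48) had the smallest p, and 1 member passed adjusted over the list alone. Without knockout 3 that list read 0.239.

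**Figure D2:**
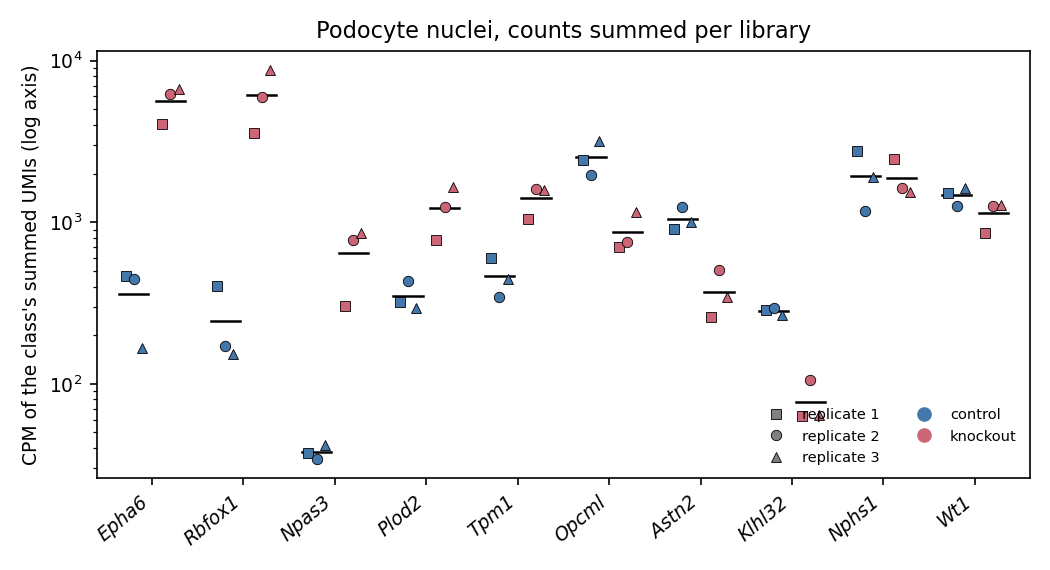
CPM (log scale) in podocytes of each control and knockout library, 1 point per library and a bar at the mean, for genes that rose or fell and for podocyte markers. Epha6 and Rbfox1 lie higher in every knockout library, and Opcml lower, while Nphs1 and Wt1 overlap.

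In parietal epithelial cells, 20 genes rose and 2 fell among 911 tested (edgeR). Tnc (ENSMUSG00000028364), the matrix protein tenascin C, rose 12.0-fold, from 429.6 ± 84.9 to 5087 ± 2075 CPM (log2 3.58 ± 0.46 SE, adjusted p = 0.00324, n = 3 per group). Cdh6, a cadherin of the developing nephron, rose 6.27-fold, from 684 ± 225 to 4492 ± 568 CPM (log2 2.65 ± 0.37 SE, adjusted p = 0.00361). Fn1, which encodes fibronectin, had 0 control and 165 knockout UMIs and was at least 31.6-fold higher against a floor of 3 UMIs over the group (adjusted p = 0.00362). The mesenchymal cadherin Cdh11 had 3 control and 178 knockout UMIs, a ratio of levels of 34.1 (95% counting interval 11.5 to 167, adjusted p = 0.00362). Nrp1, a receptor for semaphorins and VEGF, rose 6.67-fold (log2 2.74 ± 0.42 SE, adjusted p = 0.00362).

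Among the other rises in parietal epithelial cells, Map1b, a microtubule protein, had 3 control and 89 knockout UMIs (ratio 17.1, interval 5.65 to 84.3). The histone deacetylase Hdac9 had 1 and 63 (ratio 36.2, interval 6.27 to 1454). Frmd4a rose 4.88-fold, Ammecr1 9.20-fold and Rbfox1 7.41-fold (adjusted p from 0.0129 to 0.0171). Of 6 matrix and fibrosis genes 3 rose (Tnc, Fn1 and the basement membrane collagen Col4a1, log2 1.66 ± 0.39 SE, adjusted p = 0.0470), and 4 did adjusted over the list alone. As a group they passed (camera adjusted p = 0.00353, adjusted p = 0.530 with an estimated correlation). Tenm2 fell by 2.11 ± 0.42 (SE) and Park2, the ubiquitin ligase parkin, by 1.45 ± 0.35 on the log2 scale (adjusted p = 0.0171 and 0.0478). Cd44, a hyaluronan receptor used as a sign of activated parietal cells, had 0 control and 72 knockout UMIs, at least 13.8-fold higher, and did not enter the edgeR test. Cd44 also led clusters that scored highest for injured tubule, with Cdh6 among the leading genes of an unnamed one. Free RNA of such nuclei was not set apart here. Klf4 had 0 and 5 UMIs, and Nphs1 9 and 0. Stat3 read 411 ± 278 and 415 ± 51.2 CPM and was not tested, and Wt1 did not pass (log2 0.67 ± 0.50 SE, adjusted p = 0.540). Of 13 podocyte genes 0 passed (camera adjusted p = 0.810), with Cd2ap (log2 1.13 ± 0.44 SE) and Col4a3 (-0.59 ± 0.37) at the smallest p.

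These 22 calls in parietal epithelial cells rest on 143 nuclei in a single cluster, and Tnc, Cdh6, Fn1 and Cdh11 were among its leading genes. The cluster scored 1.28 for parietal epithelial cells, with 3 of their markers raised and 1 among its 10 leading genes, and nearly as high for podocytes. The name of this class is thus uncertain, and so is the cell type behind each of its values. In classes rebuilt without the called genes 14 genes passed, 11 of them among the 22. Tnc, Fn1, Cdh11 and Nrp1 passed there at an adjusted p of 0.029, and Cdh6 at 0.0368. Rbfox1 (0.0689), Tenm2 (0.0773), Park2 (0.135) and Col4a1 (0.104) did not. The count was 9 without control 1, 9 without control 3, 131 without knockout 1, 8 without knockout 2 and 7 without knockout 3. Tnc, Cdh6, Fn1, Cdh11 and Nrp1 passed in each of these fits and without control 2. The count was 75 without both libraries numbered 1, with 15 shared, and 40 with the replicate block, with 22 shared. With doublets kept it was 5, all shared, and with classes by the highest marker score 79, with 3 shared. All 13 proximal tubule transport genes were lower in knockout parietal cells (0 passed in edgeR, camera adjusted p = 0.00115, adjusted p = 0.676 with an estimated correlation), led by Slc3a1 (log2 -1.61 ± 0.63 SE) and the endocytic receptor gene Cubn (-1.42 ± 0.60). That list did not pass without control 1 (0.192) or knockout 3 (0.173).

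In the proximal tubule, which reabsorbs most of the filtrate, 1 gene rose and 4 fell among 13119 tested (edgeR). Glt1d1 (ENSMUSG00000049971), a glycosyltransferase gene, fell 8.34-fold, from 219 ± 14.6 to 26.0 ± 6.99 CPM (log2 -3.06 ± 0.22 SE, adjusted p = 0.0146, n = 3 per group). Lama3, a laminin chain, fell 5.94-fold, from 189 ± 36.2 to 31.3 ± 9.82 CPM (log2 -2.57 ± 0.26 SE, adjusted p = 0.0390). Zfp68 (ENSMUSG00000058291), a zinc-finger gene on chromosome 5, had 608 control and 0 knockout UMIs, at least 138-fold lower against a floor of 3 UMIs over the group (adjusted p = 0.0291). Its neighbour A430033K04Rik, chosen after its values were seen, had 575 and 0 UMIs and was at least 131-fold lower (adjusted p = 0.0291). Gm45083, also chosen after its values were seen, rose 10.4-fold (adjusted p = 0.0387).

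Lists of injury, cell cycle, fatty acid oxidation and transport genes passed in camera in the proximal tubule, and none did with an estimated correlation. Of 15 tubule injury genes 0 passed in edgeR and 2 did adjusted over the list alone, the injury marker Dcdc2a (log2 1.06 ± 0.14 SE, adjusted p = 0.145 over all genes) and the stress transcription factor Atf3 (1.90 ± 0.44, 0.419). The list passed upward (camera adjusted p = 0.000639, adjusted p = 0.530 with an estimated correlation). Of 20 cell cycle genes 16 were higher, 0 passed over all genes and 1 adjusted over the list alone, with Mki67 (log2 2.34 ± 0.43 SE) and Cenpf (2.05 ± 0.54) at the smallest p (camera adjusted p = 4.5e-05, adjusted p = 0.530 with an estimated correlation). Of 28 fatty acid oxidation genes 22 were lower, 0 passed over all genes and 2 adjusted over the list alone. They were the peroxisomal enzymes Acaa1b (log2 -2.11 ± 0.34 SE) and Acox3 (-0.88 ± 0.21), and the list passed downward (camera adjusted p = 0.000359, adjusted p = 0.628 with an estimated correlation). It did not pass without control 1 (0.0776) or without both libraries numbered 1 (0.118). Of 29 transport genes 0 passed in edgeR, with Slc22a30 (log2 0.55 ± 0.17 SE) and the organic anion transporter Slc22a8 (-0.72 ± 0.23) at the smallest p. Their median log2 change was -0.09 (camera adjusted p = 0.0352, adjusted p = 0.676 with an estimated correlation), and the call ended with the replicate block (0.0628) and without control 1 (0.567).

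At an unadjusted p under 0.05 there were 943 proximal tubule genes. The count was 1 without control 1, and 0 without control 2, control 3 or knockout 2, where 712, 823 and 548 genes had an unadjusted p under 0.05. It was 20 without both libraries numbered 1 and 15 with the replicate block, and both held the 5 genes. The proximal tubule cluster with the most control nuclei was led by Kap, Uqcr10 and Gm2000. A different cluster, with the most knockout nuclei, was led by Gm609, Bbox1 and Adh7. Both held nuclei of both groups, but unevenly. The cluster led by Gm609 held 75, 98 and 149 nuclei of the controls and 2906, 641 and 85 of the knockouts. Other proximal tubule clusters came mostly from 1 library. Knockout 3 gave 881 of 930 nuclei in 1 cluster and 414 of 419 in another, and control 3 gave 1168 of 1440 in yet another. Clustered without the called genes, the largest cluster held 3436, 687 and 401 nuclei of controls 1, 2 and 3. It held 3274, 751 and 121 of knockouts 1, 2 and 3.

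Summed over all nuclei, 10 genes rose and 5 fell among 16158 tested (edgeR). Sytl2, a vesicle transport gene, rose 3.85-fold, from 23.7 ± 3.14 to 91.4 ± 8.68 CPM (log2 1.94 ± 0.15 SE, adjusted p = 0.0136, n = 3 per group). C3, the central complement protein, rose 14.5-fold (log2 3.86 ± 0.41 SE, adjusted p = 0.0397). Dcdc2a, an injury marker, rose 3.30-fold (log2 1.72 ± 0.17 SE, adjusted p = 0.0356). Lockd, a transcript beside the cell cycle inhibitor Cdkn1b, rose 7.05-fold (log2 2.82 ± 0.32 SE, adjusted p = 0.0453). The other rises were Stra6l (log2 2.49), Myof, a membrane repair gene (1.75), Ankrd6 (1.76), the amino acid transporter Slc6a15 (1.63), Actn1, an actin cross-linker (1.21), and G930009F23Rik (3.77), the last chosen after its values were seen. Glt1d1 fell 9.92-fold (log2 -3.31 ± 0.25 SE, adjusted p = 0.0136), Lama3 5.01-fold (adjusted p = 0.0214) and the clock gene Ciart 3.19-fold (adjusted p = 0.0453). Zfp68 fell 237-fold, with 1140 control and 4 knockout UMIs (adjusted p = 0.0130), and A430033K04Rik fell 69.0-fold (adjusted p = 0.0130).

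Lists of proliferation, injury, inflammation and matrix genes passed upward in camera over all nuclei, and none did with an estimated correlation. These sums include the injured tubule and cycling nuclei, whose shares were 18.1-fold and 24.3-fold higher in the knockouts, so they do not show a change within a cell type. Each camera call below had an adjusted p of 0.530 with an estimated correlation unless another is given. Of 30 cell cycle genes 29 were higher, 0 passed over all genes and 23 rose adjusted over the list alone, such as Mki67 (log2 2.92 ± 0.41 SE) and Cenpf (3.13 ± 0.44, camera adjusted p = 3.8e-16). Of 24 chemokine and NF-kB genes 1 passed, C3, while 12 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.1e-10). Of 23 tubule injury genes 1 passed, Dcdc2a, and 11 rose adjusted over the list alone (camera adjusted p = 3.7e-09). Of 32 matrix and fibrosis genes 0 passed and 9 rose adjusted over the list alone, such as Fn1 (log2 1.83 ± 0.25 SE) and the fibrillar collagen Col3a1 (1.91 ± 0.28, camera adjusted p = 1.2e-06). Of 29 interferon and antigen presentation genes 0 passed and 3 rose adjusted over the list alone, with Parp14 (log2 0.97 ± 0.20 SE) and Irf1 (0.92 ± 0.22) at the smallest p (camera adjusted p = 1.1e-05). Of 26 JAK-STAT3 genes 0 passed and 5 rose adjusted over the list alone, with Birc5 (log2 2.01 ± 0.38 SE) and Icam1 (1.46 ± 0.29) at the smallest p (camera adjusted p = 0.000568). Of 15 parietal cell activation genes 0 passed and 3 rose adjusted over the list alone, with Cd44 (log2 3.45 ± 0.53 SE) and Tnc (3.38 ± 0.56) at the smallest p (camera adjusted p = 0.0110, adjusted p = 0.621 with an estimated correlation). This last list did not pass without control 2 (0.0621), control 3 (0.128) or knockout 1 (0.0925).

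Lists of fatty acid oxidation and transport genes passed downward in camera over all nuclei, and none did with an estimated correlation. Of 28 fatty acid oxidation genes 24 were lower, 0 passed over all genes and 3 fell adjusted over the list alone, with Acaa1b (log2 -2.28 ± 0.33 SE) and Acox3 (-1.004 ± 0.20) at the smallest p (camera adjusted p = 2.0e-05, adjusted p = 0.621 with an estimated correlation). Of 29 proximal tubule transport genes 19 were lower and 0 passed by either adjustment, with Slc22a8 (log2 -0.92 ± 0.23 SE) and Slc13a3 (-0.96 ± 0.25) at the smallest p (camera adjusted p = 0.00115, adjusted p = 0.621 with an estimated correlation). Of 31 distal nephron transport genes 22 were lower and 0 passed by either adjustment (camera adjusted p = 0.00294, adjusted p = 0.621 with an estimated correlation). Without control 1 these lists did not pass (0.0626, 0.277 and 0.0776), and without knockout 1 the distal list did not (0.118). Without both libraries numbered 1 they read 0.0691, 0.113 and 0.390. These sums also carry the shares of nuclei per class.

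At an unadjusted p under 0.05 there were 1523 genes over all nuclei. The count was 25 without knockout 1 and 2 without knockout 2. It was 0 without control 2, control 3 or knockout 3, where 1341, 1339 and 1151 genes had an unadjusted p under 0.05. It was 422 without both libraries numbered 1 and 283 with the replicate block, and both held the 15 genes.

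Mesangial, mural and fibroblast nuclei had 4 genes up and 1 down among 2797 tested (edgeR). Tnc had 1 control and 77 knockout UMIs, a ratio of levels of 48.0 (95% counting interval 8.36 to 1919, adjusted p = 0.0334). The basement membrane collagen Col15a1 rose 7.91-fold in the fit, with mean levels of 36.8 ± 36.5 and 366 ± 39.1 CPM (log2 2.98 ± 0.47 SE, adjusted p = 0.0407, n = 3 per group). Dclk1, a microtubule-linked kinase, rose 12.8-fold (log2 3.68 ± 0.59 SE, adjusted p = 0.0419). Gm2163, chosen after its values were seen, rose 21.9-fold (adjusted p = 0.00237). Lsamp, a cell adhesion gene, fell 6.28-fold (log2 -2.65 ± 0.41 SE, adjusted p = 0.0407). Of 18 matrix and fibrosis genes 1 rose, Tnc, while 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000359, adjusted p = 0.621 with an estimated correlation).

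At an unadjusted p under 0.05 there were 324 genes in this class. The count was 71 without control 3 and 1 without any other single library (control 1, control 2 or a knockout). It was 18 with the replicate block, the 5 among them. Without both libraries numbered 1 edgeR made 0 calls, with 230 genes at an unadjusted p under 0.05. In classes rebuilt without the called genes 6 passed, 3 of them shared, with Dclk1 and Lsamp at 0.0661. The class held 517 nuclei as tested and 857 as rebuilt, with 502 in both. Its cluster with the most control nuclei was led by Ren1 and Myh11, and a different one, with the most knockout nuclei, by Csmd1, Fhl2 and Lama2. The make-up of this pooled class may thus differ between the groups, so its values do not show a change within a cell type. Proximal tubule transport genes were lower here for 19 of 20 members (camera adjusted p = 0.000111, adjusted p = 0.621 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone, such as Slc13a3 (log2 -1.59 ± 0.33 SE) and Cubn (-1.26 ± 0.37).

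In endothelial nuclei edgeR called 0 of 5257 genes, with 201 at an unadjusted p under 0.05 and 1 by DESeq2. The genes with the smallest p were Glt1d1 (log2 -2.84 ± 0.43 SE, adjusted p = 0.193), Slc6a15 (1.54 ± 0.30, 0.563), Rhobtb1 (1.17 ± 0.25, 0.708) and Igfbp5, which binds insulin-like growth factors (-1.21 ± 0.27, 0.791). The fifth, the synaptic adhesion gene Lrfn2, had 2 control and 58 knockout UMIs (ratio 28.4, 95% counting interval 7.52 to 240.2). With the replicate block 63 genes passed, these 5 among them at adjusted p from 0.000253 to 0.00713. All 6 tubule injury genes tested were higher, 0 over all genes and 3 adjusted over the list alone, with the macrophage growth factor gene Il34 (log2 1.07 ± 0.25 SE) and the leukocyte adhesion gene Vcam1 (1.76 ± 0.43) at the smallest p. The list passed (camera adjusted p = 0.000541, adjusted p = 0.530 with an estimated correlation). Free RNA of injured tubule nuclei, whose share was 18.1-fold higher in the knockouts, was not set apart here.

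In immune nuclei edgeR called 0 of 1917 genes and DESeq2 0 of 16739, with 108 at an unadjusted p under 0.05 in edgeR. Genes with small p were Dnase1 (log2 -2.95 ± 0.60 SE, adjusted p = 0.182), Lama3 (-2.43 ± 0.63), Slc6a15 (1.58 ± 0.41) and the endocytic adaptor Dab2 (0.86 ± 0.23), the last 3 at an adjusted p of 0.646. Tubule genes such as Dnase1 read in this class may come from free RNA. In immune nuclei 5 genes passed with the replicate block and 2 without knockout 1.

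In the distal nephron, Glt1d1 was the single gene past the threshold. In the thick ascending limb, which takes up salt, it fell 7.18-fold, from 71.6 ± 16.8 to 9.31 ± 1.29 CPM (log2 -2.84 ± 0.37 SE, adjusted p = 0.0463, 1 of 7135 genes). In intercalated cells, which handle acid and base, it fell 6.29-fold, from 179.7 ± 14.3 to 29.5 ± 12.1 CPM (log2 -2.65 ± 0.28 SE, adjusted p = 0.00175, 1 of 6644 genes). Free proximal tubule RNA may carry both falls. In the controls Glt1d1 read 0.327 and 0.821 of its proximal tubule level in these 2 classes, and the median proximal tubule transport gene 0.356 and 0.727. Free RNA at those shares would give log2 changes of -3.56 and -2.37. In the distal convoluted and connecting tubule edgeR called 0 of 6915 genes and DESeq2 0 of 20600, with 313 at an unadjusted p under 0.05 in edgeR. The smallest p there were those of the nuclear protein gene Tox (log2 3.13 ± 0.44 SE, adjusted p = 0.0723), Il34 (1.55 ± 0.25), Glt1d1 (-2.34 ± 0.44), Gabarapl1, an autophagy gene (-0.91 ± 0.18), and Ppat, of purine synthesis (-0.94 ± 0.19). In principal cells, which take up water and sodium, edgeR called 0 of 2896 genes and DESeq2 0 of 17152, with 177 at an unadjusted p under 0.05 in edgeR. The smallest p there were those of Setd5 (log2 1.45 ± 0.29 SE, adjusted p = 0.111), the matrix gene Npnt (1.49 ± 0.30), Ypel2 (1.49 ± 0.30), Tbc1d2 (-1.99 ± 0.41) and the calcium-binding protein gene Calb1 (-1.95 ± 0.39).

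The list of tubule injury genes passed upward in camera in 2 distal classes. It did not in intercalated cells (4 of 6 members higher, camera adjusted p = 0.0771) and was not tested in principal cells, with 3 members. All 7 tested in the distal convoluted and connecting tubule were higher, 0 over all genes and 2 adjusted over the list alone, Il34 among them (camera adjusted p = 0.000225, adjusted p = 0.530 with an estimated correlation). All 6 tested in the thick ascending limb were higher, 0 over all genes and 2 adjusted over the list alone, with Dcdc2a (log2 2.47 ± 0.37 SE) and Il34 (0.91 ± 0.29) at the smallest p (camera adjusted p = 0.00231, adjusted p = 0.530 with an estimated correlation). That call ended without control 2 (0.0940), control 3 (0.0914), knockout 1 (0.112) or knockout 2 (0.125). In neither class was free RNA of injured tubule nuclei set apart. Proximal tubule transport genes were lower in all 4 distal classes. They were lower for 24 of 27 members in the thick ascending limb (camera adjusted p = 3.0e-06), led by Slc16a9 (log2 -1.89 ± 0.43 SE) and Slc13a3 (-1.30 ± 0.28). They were lower for 22 of 26 in the distal convoluted and connecting tubule (0.000359), 13 of 15 in principal cells (0.000359) and 25 of 27 in intercalated cells (1.0e-08), there led by Slc13a3 (-1.05 ± 0.25) and Slc22a8 (-0.94 ± 0.22). With an estimated correlation the adjusted p was 0.621, 0.676, 0.639 and 0.530 in that order. Over the list alone, 2, 0, 0 and 5 members passed, and over all genes 0 in each. In the distal convoluted and connecting tubule the call ended without control 1 (0.136) or knockout 3 (0.0759).

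At an unadjusted p under 0.05 there were 376 genes in the thick ascending limb and 464 in intercalated cells. In the thick ascending limb edgeR made 0 calls without control 1 (349 genes at an unadjusted p under 0.05), control 2 (335), control 3 (502), knockout 2 (244) or knockout 3 (162), and Glt1d1 read adjusted p from 0.118 to 0.425. Without knockout 1 it called 2 genes, Glt1d1 (0.0760) not among them. In intercalated cells 2 genes passed without control 1 and 2 without knockout 1, and 1 without any other library. Without knockout 1 there were 6 calls in the distal convoluted and connecting tubule and 24 in principal cells. With the replicate block there were 12 calls in the thick ascending limb, 59 in the distal convoluted and connecting tubule, 41 in principal cells and 26 in intercalated cells. Without both libraries numbered 1 there were 10, 2, 4 and 0 in that order, the 0 with 448 genes at an unadjusted p under 0.05. Of the intercalated cell clusters, the one with the most control nuclei was led by Slc26a4. A different one, with the most knockout nuclei, was led by Kit and Clnk. Leading genes were taken over the nuclei of both groups together, so they show no change within a cluster.

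**Figure D3:**
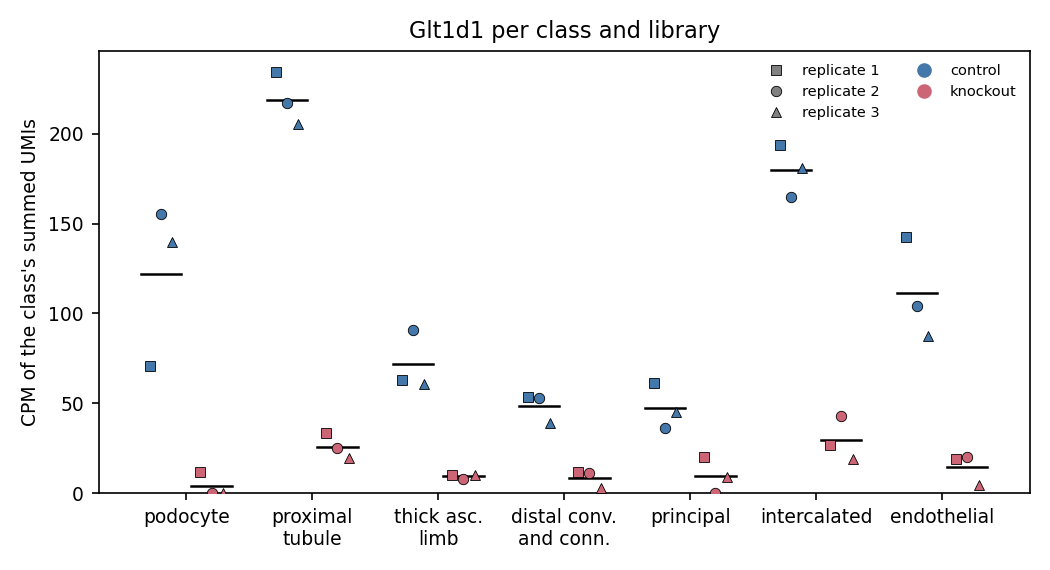
CPM of Glt1d1 in each class of each control and knockout library, 1 point per library and a bar at the mean. The mean was lower in the knockouts in each class drawn, with the lowest control mean 47.4 CPM in principal cells and the highest knockout mean 29.5 CPM in intercalated cells.

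Over 145 tests of lists in classes, camera called 52, 22 upward and 30 downward. With an estimated correlation 0 passed, and with fry 0 passed. A call with the preset correlation of 0.01 takes members of a list to be nearly independent between mice. With the replicate block 70 lists passed, 51 of them shared with the 52.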

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

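The tests below of Klf4 loss and of a strain or transgene difference were chosen only after the result was seen, while the test of a wider stretch and the splits of the libraries were set before.

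The change between knockout and control differed between podocytes and parietal epithelial cells for 17 of 2033 genes (edgeR interaction, adjusted p under 0.05; 188 at an unadjusted p under 0.05). The change was higher in parietal cells for 14, such as the adhesion genes Cdh6 (log2 difference 4.89 ± 0.89 SE, adjusted p = 0.000768) and Nrp1 (3.12 ± 0.52, 0.000353). It was higher in podocytes for 3, Nckap5 (log2 difference -2.67 ± 0.51 SE, adjusted p = 0.00139), Npas3 (-3.30 ± 0.77, 0.0141) and Klhl29 (-2.54 ± 0.66, 0.0449). Npas3 and Klhl29 had no value in the fit of parietal cells alone, and Cdh6 had none in that of podocytes. Klhl29 changed by log2 0.34 in podocytes, so its difference does not show a rise there. Of the 10 splits of the 6 libraries, the real one gave 17 genes and the highest other 1, and 10 splits are too few for a share under 0.05. The other 3 splits that part all 3 pairs gave 0 genes each.

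The change differed between podocytes and proximal tubule for 25 of 11294 genes (570 at an unadjusted p under 0.05). Rbfox1 (log2 difference -4.67 ± 0.46 SE, adjusted p = 1.3e-20), Epha6 (-3.54 ± 0.46, 4.8e-11) and Npas3 (-3.35 ± 0.51, 1.4e-07) had the higher change in podocytes. The change of Klhl32 was lower in podocytes (2.82 ± 0.45, 7.8e-07). In all, the change was higher in the proximal tubule for 7 genes and lower for 18. Of the 10 splits, 3 gave as many genes, and 10 splits are too few for a share under 0.05. Here and for podocytes against parietal cells, both classes come from the same 6 mice, and the adjusted p values may overstate the evidence. The highest other count was 55, in the split that sets controls 1 and 2 with knockout 1. That split keeps both libraries numbered 1 together, and the others that do so gave 27, 3 and 3 genes. This may point to a structure of the samples. The other splits that part all 3 pairs, as the real one does, gave 0, 1 and 0 genes.

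Zfp68 and A430033K04Rik, the second chosen after its values were seen, were among the 25 genes, with adjusted p of 0.00328 and 8.7e-06. They lie 3097 bp apart on chromosome 5 and had 2161 control and 16 knockout UMIs in all nuclei, 10 of the 16 in podocytes (40.7 CPM in control and 18.4 in knockout podocytes, from 21 and 10 UMIs), which held 0.922% of the knockout UMIs of all genes. The tables argue against Klf4 loss lowering the pair within podocytes as far as it fell outside them. Those 10 UMIs stood against 0.0683 expected at the fall seen outside podocytes (upper Poisson limit 1). A smaller effect of Klf4 loss within podocytes, such as from 40.7 to 18.4 CPM, was not excluded. An indirect effect of that loss on the other cells, where the fall lies, was not tested by this comparison. The tables also argue against a broad change of levels over a wider stretch. Of 36 genes tested within 1 Mb, 4 had an unadjusted p under 0.05, 1.18 times the share elsewhere (11.1 against 9.41%, Fisher exact p = 0.772). A wider difference in sequence that leaves most levels unchanged cannot be excluded this way, and 15 nearby genes had no coordinates. A strain or transgene difference at the locus stays open: of the classes other than podocytes with at least 20 control UMIs of the pair, the lowest bound on the fall was at least 15-fold against a floor of 3 UMIs over the group, in endothelial nuclei with 46 control and 0 knockout UMIs. Intercalated nuclei kept 2 UMIs (44.9 and 1.43 CPM) and distal convoluted and connecting tubule nuclei 1 (36.2 and 0.583 CPM). One hypothesis is that the podocyte-driven transgene may lie at this locus, silencing the pair more outside podocytes than in them, and no sequence at the locus was read to test it.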

How the results depend on the processing

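Classes rebuilt without the called genes and clustering with those genes were chosen after seeing the data, while the other alternatives were set before. The values below are ordered all nuclei, podocytes, parietal epithelial cells, proximal tubule, endothelial cells, mesangial, mural and fibroblast nuclei, immune cells, thick ascending limb, distal convoluted and connecting tubule, principal cells and intercalated cells, with 15, 15, 22, 5, 0, 5, 0, 1, 0, 0 and 1 changed genes as reported.

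With the replicate block the counts were 283, 18, 40, 15, 63, 18, 5, 12, 59, 41 and 26. DESeq2 gave 433, 43, 14, 111, 1, 17, 0, 3, 0, 0 and 25. Without a low-count filter they were 60, 85, 61, 13, 27, 83, 2, 95, 67, 21 and 107, with more genes tested. With at least 500 genes per nucleus they were 15, 15, 9, 5, 0, 1, 0, 0, 1, 0 and 1, and with doublets kept 26, 5, 5, 5, 0, 2, 0, 0, 0, 0 and 1. With RLE scaling they were 15, 16, 20, 5, 0, 5, 0, 1, 0, 0 and 1, all within 1.5 times. Without both libraries numbered 1 they were 422, 239, 75, 20, 0, 0, 3, 10, 2, 4 and 0. By the highest marker score the 10 classes, all nuclei left out, gave 14, 79, 4, 3, 0, 4, 3, 4, 1 and 1, with 4 of the 15 podocyte genes and 3 of the 22 parietal genes among them. In rebuilt classes they gave 16, 14, 5, 0, 6, 0, 2, 1, 0 and 2. Leaving out 1 library gave ranges of 0 to 25, 0 to 294, 7 to 131, 0 to 4, 0 to 0, 1 to 71, 0 to 2, 0 to 2, 0 to 6, 0 to 24 and 1 to 2, from fewer samples. Beyond the genes or samples each setting leaves, the cause was not tested.

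Of the 55 named genes past the threshold, 54 kept their call with RLE scaling, 54 without a low-count filter, 53 with the replicate block and 50 with DESeq2, all in the same direction. With at least 500 genes per nucleus 42 kept it, with doublets kept 33 of 53, without both libraries numbered 1 47 of 53, and in rebuilt classes 32 of 38. By the highest marker score 11 of 39 did. Over the 6 fits that leave out 1 library, 120 of 326 values kept the call, all in the same direction.

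None of the reversed log2 values was past the threshold in either fit except Hdac9, called as reported. By the highest marker score Nphs1 in podocytes read 0.12 on the log2 scale, Bcl2l1 in podocytes -0.012, and in parietal epithelial cells Hdac9 -0.19 and Col4a3 0.076. Without both libraries numbered 1 Stat3 in podocytes read -0.035. Leaving out 1 library gave -0.32 to 0.29 for Nphs1 and -0.085 to 0.47 for Stat3, both in podocytes. The podocyte list in podocytes had adjusted p from 0.00739 without control 1 to 0.781, with its direction reversed without control 2 (0.512), and in parietal epithelial cells it reversed by the highest marker score (0.0748). The difference in podocyte share was -0.395 percentage points by the highest marker score, and -0.272 with nuclei other than proximal tubule as denominator. The cause was not tested.

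Of 145 tests of lists 52 passed. The count was 0 with an estimated correlation and 0 with fry, and the cause was not tested. It was 70 with the replicate block, 48 with at least 500 genes per nucleus, 58 by the highest marker score, 51 in rebuilt classes, 45 without both libraries numbered 1 and 37 to 62 without 1 library.

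The number of classes whose libraries did not overlap was 2 of 13. It was 4 by the highest marker score, 5 with nuclei other than proximal tubule as denominator, 7 without both libraries numbered 1 and 2 to 6 without 1 library, where chance gives larger fractions (0.333 and 0.2). It was 2 with at least 500 genes per nucleus, doublets kept, or clustering with the called genes. The injured tubule difference was 6.29 percentage points as reported, 5.93 clustered with the called genes, 6.78 by the highest marker score and 11.7 with nuclei other than proximal tubule as denominator, and the cycling difference 1.90, 3.81, 4.86 and 3.31 in that order. In edgeR fits on nuclei per class, the injured tubule and cycling shares passed at log2 changes of 4.14 and 4.52, and with the replicate block at 4.12 and 4.29, where the exact permutation test cannot pass with 3 against 3. The difference of Klf4 in podocytes kept its direction under all 10 alternatives, whose permutation tests cannot pass with so few libraries. The level in each was not set against a floor.

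A sex covariate was not run, since all 6 libraries read as male. Some alternatives gave no value for genes below their count filter or in classes with too few nuclei: mainly Hdac9, Ammecr1, Cd2ap and Slc3a1 in parietal epithelial cells, Lrfn2 in endothelial cells, Lama3 and Dnase1 in immune cells, and Atf3, Mki67 and Cenpf in the proximal tubule. Depth limited Klf4 in podocytes, where 3 UMIs stand for 8.10 CPM in the controls, and parietal epithelial cells, where 911 genes were tested against 13119 in the proximal tubule.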

Other observations

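The tests in the paragraphs on clock genes and on proximal tubule RNA were chosen only after the result was seen, and the splits of the libraries were set before the data were examined.

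Of 15 clock genes tested over all nuclei 1 passed, Ciart (log2 -1.67, adjusted p = 0.0453). Arntl (log2 1.98, adjusted p = 0.0774), Npas2 (1.39, 0.0925) and Dbp (-1.89, 0.147) did not, and did with the replicate block (0.00778, 0.0300 and 0.0105). Nfil3 (log2 2.36, adjusted p = 0.251), Nr1d1 (-1.37, 0.266) and Hlf (-0.99, 0.310) passed in neither fit. Arntl, Dbp, Ciart and Tef defined the phase, and 10 of the 11 other genes had its sign. A response of the proximal tubule alone cannot be told apart, since free proximal tubule RNA reaches other classes. Over the 4 other tubule classes the median log2 change of Dbp was -1.49 (median SE 0.41), and -0.82 beyond that expected from free RNA, its share set by the median proximal tubule transport gene in each class, while for Tef the latter was 0.00026 (median SE 0.22). In the thick ascending limb alone both lay beyond free RNA (Dbp -1.41 ± 0.42 SE, Tef -0.67 ± 0.22), on an assumed share of free RNA. Collection at another time of day stays open, since 82.8% (24 of 29) of the changes of the other clock genes over 5 classes had the sign of that phase, though changes from the same 6 libraries are not independent. Times of collection are not in the labels, so a shift of the clock by the knockout itself could not be set against it.

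Proximal tubule transport genes were lower in knockout nuclei of classes that do not use them, while in the proximal tubule itself their median log2 change was -0.087. Lower transcription in the proximal tubule alone was argued against by that value, since the median of the other classes' medians was -0.63. In 9 of 9 classes outside the proximal tubule the median fell further than in it, so less free proximal tubule RNA in the knockout libraries may be the cause and stays open. Against it, the level of the median transport gene relative to the proximal tubule was not lower in endothelial nuclei (0.656 in control and 0.685 in knockout libraries) and nearly alike in immune nuclei (1.21 and 1.17). A biological cause of less free RNA, such as tubule injury, was not tested.

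For the counts of changed genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split and the highest other gave 15 and 0 genes in all nuclei, 15 and 0 in podocytes, 22 and 0 in parietal epithelial cells and 5 and 0 in the proximal tubule. They gave 5 and 0 in mesangial, mural and fibroblast nuclei, 1 and 0 in the thick ascending limb and 1 and 0 in intercalated cells, so 1 split, the real one, gave as many in each of these 7 comparisons. In classes where edgeR called 0 genes all 10 splits gave as many, with the highest other 2 in endothelial nuclei (201 genes at an unadjusted p under 0.05 in the real split, DESeq2 1), 3 in immune nuclei (108, DESeq2 0), 13 in the distal convoluted and connecting tubule (313, DESeq2 0) and 6 in principal cells (177, DESeq2 0). For gene lists, 2 of the 10 splits gave as many, with 52 in the real split and 57 in the highest other. Each of these 5 highest others came from the split that sets controls 1 and 2 with knockout 1, which keeps the libraries numbered 1 together. The other splits that keep them together gave 45, 42 and 29 lists, and 0 genes in each of these classes. A structure of the samples is thus possible, but keeping these libraries together does not by itself account for the gene counts. Within the replicate block 70 lists passed. The other splits that part all 3 pairs gave 23, 19 and 9 lists and 0 genes in each class.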
